A study of Mus musculus with 28 samples.

How the data were processed

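RNA sequencing was done on 28 libraries from livers of mice carrying a c-Myc transgene together with Alb-cre, a Cre recombinase driven by the albumin promoter. The labels name 14 libraries of hepatocellular carcinoma tissue and 14 of peritumour tissue. Titles give a group and a replicate number: 11 Tu_F, 11 Pe_F, 3 Tu_M and 3 Pe_M libraries, where Tu is tumour and Pe peritumour. The labels do not expand the letters F and M, which are used here as they stand. Each tumour library shares a sample code with 1 peritumour library, and the code was taken as the animal, giving 14 pairs. The codes come in 2 styles, the first in 12 libraries (F replicates 1 to 3 and all M) and the second in 16 (F replicates 4 to 11). Code style was treated as a possible batch, balanced over tissue, and every M library has the first style.

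Per the labels' protocols, total RNA was extracted with Trizol, mRNA was selected with oligo(dT) beads, cDNA was primed with random hexamers, and amplified products were made into single-strand circles. Whether strand was kept is not given in the sources used here, so a gene and its antisense partner cannot be told apart. HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5 are named per the submitters' processing notes, without their roles. The authors deposited estimated counts per gene and library with 2 decimals, per the file headers, and 8.06% of these values are not whole. The authors' deposited table also gives a log2 fold change with a p-value and q-value for tumour against peritumour and for M against F in each tissue, in columns named for degseq. Their mean columns for Tu_F and Pe_F equal the means of 10 libraries without replicate 6 of F, while the other means take every library. The table has 3 mean columns and 6 comparison columns of a further group, Li, which has no sample among the labels, and these were not used here.

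The table held 18182 protein-coding genes with Entrez gene IDs, after 1 line without a gene ID was left out. In 26 cases a symbol had turned into a date and was looked up again by gene ID. Gene IDs of 18060 genes were found in the reference table. Coordinates are those of the deposited table, on GRCm38. Library totals ran from 14777567 to 17576921 estimated counts, and the top 10 genes of a library held 6.2% to 11.5% of its total. Expression is given as counts per 1e6 (CPM). No 2 libraries of the same group agreed within sampling noise; the lowest index of dispersion over all such pairs of libraries was 18.

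Estimated counts were rounded to whole numbers. The test was edgeR 4.0.16 in R 4.3.3: TMM factors (0.809 to 1.36), filterByExpr, which left 14117 genes, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Tumour was compared with peritumour over all libraries with code style and letter as covariates. Contrasts between the 4 groups came from 1 fit with code style as a covariate. These designs, the gene lists, the rule for named genes and most of the alternative settings were fixed before the data were examined.

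Pairing was then checked. Within every pair the deviations of the 2 libraries from the means of their group and code style were correlated over genes (0.135 to 0.61, median of unpaired libraries -0.0171), and 10 of 14 tumour libraries correlated best with their own peritumour library. With the animal as a block, the biological coefficient of variation was 0.27, against 0.381 without it. The paired fit, planned as an alternative, is therefore given beside the unpaired one. Its own alternatives, the named gene rule applied to it, and the tests per pair described next were added after the data were seen.

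37 gene lists were used. Members were counted as higher, lower or not passing. A list was set against all other genes with camera (limma 3.58.1), at a preset correlation of 0.01 and again with an estimated correlation. This was done where at least 3 members were tested, which held for 35 lists. For 36 lists the mean log2 CPM (prior count 2) of the tested members was taken per library. The tumour minus peritumour difference per animal was tested by a two-sided exact test over all 16384 sign flips, with Benjamini-Hochberg adjustment over the 36 lists. M and F animals were compared on the same scores by a two-sided exact permutation test over 364 splits. Within the first code style, 3 against 3 animals, the smallest p such a test allows is 0.1. KEGG pathways annotated in the deposited table with at least 10 tested genes (254) were tested like the lists. Intervals of a mean over pairs are 95% intervals from the t distribution.

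Named genes were, per comparison, the 5 largest rises and 5 largest falls with a mean of at least 10 CPM, leaving out predicted genes and those without a usual symbol. From each list up to 2 risen and 2 fallen members with the smallest adjusted p were added. Myc, Afp, Gpc3, Cd274, Pdcd1, Foxp3, Cd8a, Clec4f, Ly6g and Krt19 were always included, and for M against F also Xist and 4 Y-linked genes. Pdcd1 did not pass the expression filter, and Xist was not analysed here. Some genes that the rule names are not reported here.

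The alternatives were DESeq2 1.42.0, RLE factors, scaling by library size alone, no expression filter, no covariates, the replicate block, each code style alone, the F or M libraries alone, an added fold change limit of 1 on the log2 scale, and leaving out libraries or pairs in turn. A count under an alternative was taken as the same within a factor of 1.5. A gene or list that did not pass was taken to have no direction. Each test was first run on simulated counts with 200 changed genes and the real library sizes. For tumour against peritumour over all libraries (14027 genes in that step), 25.4% of genes changed 1.5-fold, 77.6% changed 2-fold and 100% changed 4-fold were recovered, and in the paired fit 64.2%, 88.1% and 100%. For Tu_F against Pe_F these shares were 20.9%, 71.6% and 97%. For Tu_M against Pe_M (14012 genes) they were 1.5%, 13.4% and 59.1%, and for the difference between M and F in the tumour effect 1.5%, 9% and 57.6%. With the animal as a block these 2 comparisons recovered 4.5%, 41.8% and 78.8%, and 1.5%, 37.3% and 71.2%, with 1 false call of 84 and 4 of 77. For Tu_M against Tu_F they were 4.5%, 29.9% and 65.2%, and for Pe_M against Pe_F (14033 genes) 3%, 22.4% and 78.8%. False calls numbered 0 of 135 without pairing and 3 of 171 in the paired fit. They were 1 of 127, 0 of 49 and 0 of 45 in the next 3 comparisons without the block. Calls outside the 200 changed genes were 9 of 75 for Tu_M against Tu_F and 6 of 75 for Pe_M against Pe_F. The simulated counts kept the fitted level of each animal, Y-linked genes included. The calls of these last 2 comparisons may therefore hold real differences between M and F, and they are not rates of false calls. A simulated changed list of 20 genes was found by both list tests, and 0 of 35 unchanged lists passed. Genes were drawn independently and the unchanged lists at random, so this step cannot show how either test behaves on lists of correlated genes. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.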

Results

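Gene expression was measured in 14 tumours and in the liver tissue next to each of them, in mice with a liver-directed c-Myc transgene. Of the 14 animals, 11 carry the letter F and 3 the letter M in their labels. Each library had counts for 15141 to 16431 genes. The series design names the comparison of tissue inside the tumour with tissue around it, and the title places the interest on immune-related genes.

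Myc itself was abundant in both tissues. It measured 460 ± 135 CPM (SD, n = 11) in Tu_F, 378 ± 137 CPM (SD, n = 11) in Pe_F, 451 ± 188 CPM (SD, n = 3) in Tu_M and 313 ± 47.9 CPM (SD, n = 3) in Pe_M. Tumour was the higher member in 10 of 14 pairs. The log2 fold change was 0.34 ± 0.18 (SE) without pairing, adjusted p = 0.299 (edgeR), and 0.34 ± 0.10 (SE) with the animal as a block, adjusted p = 0.036 (edgeR). Myc lies on chromosome 15 at 61985341 to 61990472 (gene ID 17869), and whether transgene reads count toward it is not given in the sources used here. Afp, the fetal liver albumin homologue used as a tumour marker, ranged from 2.35 to 11104 CPM over the libraries, with adjusted p = 0.246 (edgeR) for tumour against peritumour.

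The question of what separates tumour from peritumour tissue was asked over all 28 libraries. Among the genes with the largest changes, Muc13, Vil1 and Tff3 rose in tumour, and Gdf10, Dcn and Tbx3 fell. Muc13, a membrane mucin, averaged 21.5 ± 28.8 CPM in tumour and 1.22 ± 1.08 CPM in peritumour tissue (SD, n = 14 each) and was higher in 11 of 14 pairs. Tff3, a secreted trefoil peptide of mucous epithelia, averaged 295 ± 300 CPM against 54.5 ± 44 CPM (SD, n = 14 each), also higher in 11 of 14 pairs. In the opposite direction, Dcn, which encodes the matrix proteoglycan decorin, averaged 109 ± 54.1 CPM in tumour and 233 ± 95.8 CPM in peritumour tissue (SD, n = 14 each) and was lower in 13 of 14 pairs. Tbx3, a transcription factor of pericentral hepatocytes, and Lrat, the retinol-esterifying enzyme of stellate cells, were lower in all 14 pairs.

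In edgeR's test without pairing, 114 genes were higher and 34 lower in tumour at the adjusted threshold, out of 2672 genes with an unadjusted p under 0.05. The largest rises were those of Muc13 (4.17 ± 0.72, log2 fold change ± SE), Vil1, the microvillus protein villin (2.71 ± 0.69), Tff3 (2.29 ± 0.47), Fam107a (2.11 ± 0.41) and the annexin Anxa13 (2.07 ± 0.44). The largest falls were those of Gdf10, a TGF-beta family ligand (-1.33 ± 0.31), Dcn (-1.11 ± 0.24), Tbx3 (-1.03 ± 0.24), Lrat (from 15.4 to 7.68 CPM) and Serpina7, thyroxine-binding globulin (from 35.4 to 17.7 CPM). Among list members, the cytokine Il1a fell (-0.73 ± 0.19) and Apln, the vascular ligand apelin, rose (1.73 ± 0.39). Their adjusted p values (edgeR) ran from 0.0391 to 0.0497, close to the threshold. The count was 0 without F replicate 1, F replicate 7, F replicate 8, M replicate 2 or M replicate 3, and at most 4 without F replicate 2, 6, 9, 10 or 11. It was 246 without F replicate 5.

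With the animal as a block, the same comparison called 789 genes higher and 835 lower (edgeR), and DESeq2 called 2387 genes. Scaling by library size alone moved the split of that fit to 1151 higher and 677 lower. The paired fit kept Muc13 (3.26 ± 0.73), Tff3 (2.21 ± 0.57), Fam107a (1.88 ± 0.34) and Anxa13 (1.76 ± 0.34) among the largest rises and added Hif3a, a hypoxia-inducible factor subunit (2.45 ± 0.49). The largest falls were in Mup10 (-2.31 ± 0.38), Mup16 (-2.14 ± 0.37), Cyp2c50 (-1.99 ± 0.35), Cyp2c54 (-1.84 ± 0.32) and Serpina3k (-1.82 ± 0.30). These 5 belong to families of near-identical copies, the major urinary proteins, Cyp2c enzymes and Serpina3 inhibitors, so the share of reads given to each copy is uncertain. Muc13 lies on chromosome 16 at 33794037 to 33819929 (gene ID 17063) and Tff3 on chromosome 17 at 31125306 to 31129611. Among the libraries of the first code style alone the paired fit called 0 genes (edgeR), with 1199 at an unadjusted p under 0.05, and in those of the second style alone it called 981.

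**Figure D1:**
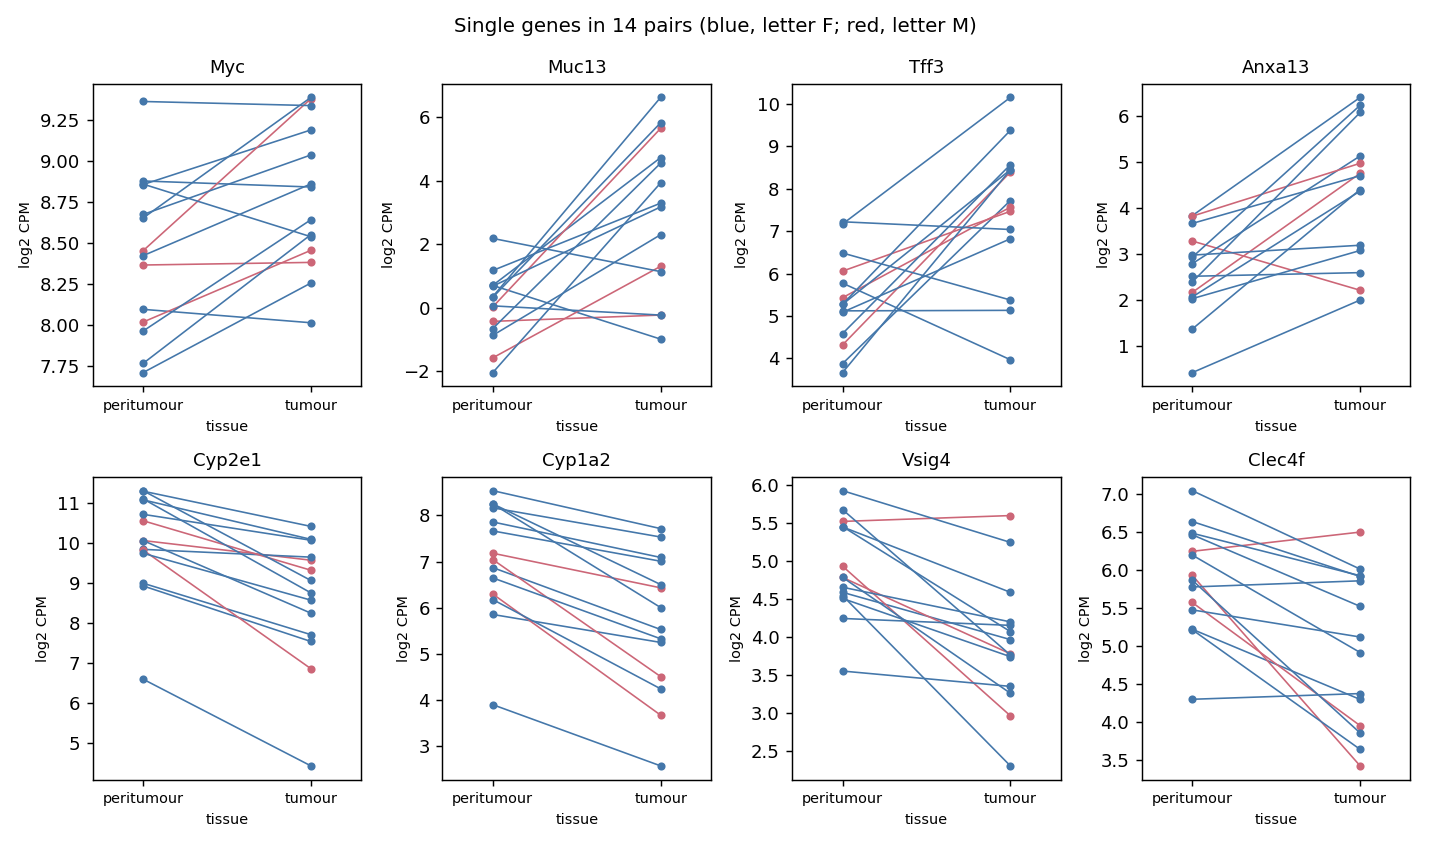
Normalised expression of 8 genes in the 14 animals, on a log2 CPM axis that differs between panels; each line joins the peritumour and tumour library of 1 animal, blue for the letter F and red for M. Muc13 was higher in tumour in 11 of 14 pairs and Anxa13 in 13, while Cyp2e1 and Cyp1a2 were lower in all 14.

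Hepatocyte genes were lower in tumour, most of all those expressed around the central vein. The pericentral list fell by 0.956 on the log2 scale per pair (SD 0.618, 95% interval -1.31 to -0.6), in 14 of 14 pairs (exact sign-flip p = 0.000122, the smallest these flips can give; adjusted p = 0.000879 over 36 lists). In the paired fit 9 of its 10 members fell (10 adjusted over the list alone), among them Cyp2e1, the ethanol-inducible P450 (-1.41 ± 0.20, from 1325 to 565 CPM), Cyp1a2 (-1.37 ± 0.18) and Tbx3 (-1.06 ± 0.13). The bile acid, urea cycle and P450 list, which shares Cyp2e1 and Cyp1a2, fell by 0.757 (SD 0.424) in 14 of 14 pairs (exact adjusted p = 0.000879), with 12 of 16 members lower and 13 adjusted over the list alone. The periportal list had a mean difference of -0.21 (SD 0.491; exact adjusted p = 0.252), with Pck1, the gluconeogenic enzyme, the single member lower of 8 (-0.86 ± 0.25). The periportal mean was -0.12 without F replicate 2 and -0.02 without F pairs 2, 5 and 6, where the pericentral mean was -1.04. Hepatocyte identity genes fell by 0.397 (SD 0.369) in 13 of 14 pairs (exact adjusted p = 0.00126), with 7 of 16 members lower, such as Tat (-0.79 ± 0.14) and Hpd (-0.68 ± 0.14), both of tyrosine breakdown. The fall was present in both code styles: the pericentral mean was -1.01 in the first and -0.92 in the second, and the P450 list mean was -0.69 and -0.81.

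Liver genes that differ between the sexes fell in tumour whichever sex they favour. The male-biased list fell by 0.753 (SD 0.567) in 14 of 14 pairs (exact adjusted p = 0.000879) and the female-biased list by 0.818 (SD 0.47) in 13 of 14 (exact adjusted p = 0.00126). In the paired fit 5 of 11 and 6 of 13 members were lower, and 7 and 9 adjusted over the list alone. Examples were Mup20 (-1.77 ± 0.22), Cyp2d9 (-0.99 ± 0.16), Cyp2b9 (-1.49 ± 0.20) and Cyp4a14 (-1.38 ± 0.21), all from families with close copies. Of the male-biased list, 1 member was higher when adjusted over the list alone.

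Transcripts of the complement and acute phase lists were lower on average as well. Complement genes fell by 0.36 (SD 0.369) and acute phase genes by 0.56 (SD 0.457), each in 14 of 14 pairs (exact adjusted p = 0.000879 for both). In the paired fit 7 of 18 complement members were lower, among them the lectin Mbl1 (-0.86 ± 0.17) and C8a of the membrane attack complex (-0.76 ± 0.16). Of the acute phase genes 6 of 13 were lower (9 adjusted over the list alone), among them Saa1 (-1.04 ± 0.19) and Apcs (-0.91 ± 0.17).

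Myc target and ribosome biogenesis genes rose by 0.169 on the log2 scale (SD 0.181), in 12 of 14 pairs (exact adjusted p = 0.0101), the 1 list of 36 that rose. In the 11 F pairs alone its mean was 0.14 (SD 0.165) and it did not pass (exact adjusted p = 0.0668). In the paired fit 7 of its 18 members were higher, 10 adjusted over the list alone, among them Mybbp1a (0.37 ± 0.07), higher in 14 of 14 pairs, and the nucleolar methyltransferase Nop2 (0.33 ± 0.07). Cell cycle genes had a mean difference of 0.20 (SD 0.378; exact adjusted p = 0.15), and the replication helicase genes Mcm2 (0.36 ± 0.07) and Mcm4 (0.33 ± 0.10) were the 2 of 22 that passed. Fatty acid oxidation genes fell by 0.212 (SD 0.325) in 12 of 14 pairs (exact adjusted p = 0.0268), with 3 of 11 members lower, such as Ehhadh (-0.56 ± 0.13) and Hadhb (-0.30 ± 0.08). Their mean was -0.14 without F replicate 2. The list did not pass without M replicate 2 (-0.21, exact adjusted p = 0.0511), without F pairs 2, 5 and 6 (-0.12, exact adjusted p = 0.0887) or in F pairs alone (-0.22, exact adjusted p = 0.112). Lipid and cholesterol synthesis genes (-0.16, SD 0.339; exact adjusted p = 0.201) and glycolysis genes (0.11, SD 0.188; exact adjusted p = 0.132) did not pass as lists, though the first did without F replicate 5 (exact adjusted p = 0.0136) and without F pairs 2, 5 and 6 (0.0258). In it 4 of 15 members were lower, including Elovl6 (-0.53 ± 0.12) and Hmgcs1 (-0.41 ± 0.09). Of the tumour and fetal liver markers (0.25, SD 0.932; exact adjusted p = 0.429; 0.07 without F replicate 4), Golm1 rose (0.49 ± 0.12) and Ly6d fell (-1.26 ± 0.25), while Gpc3 did not pass (-0.17 ± 0.35, adjusted p = 0.792, edgeR).

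**Figure D2:**
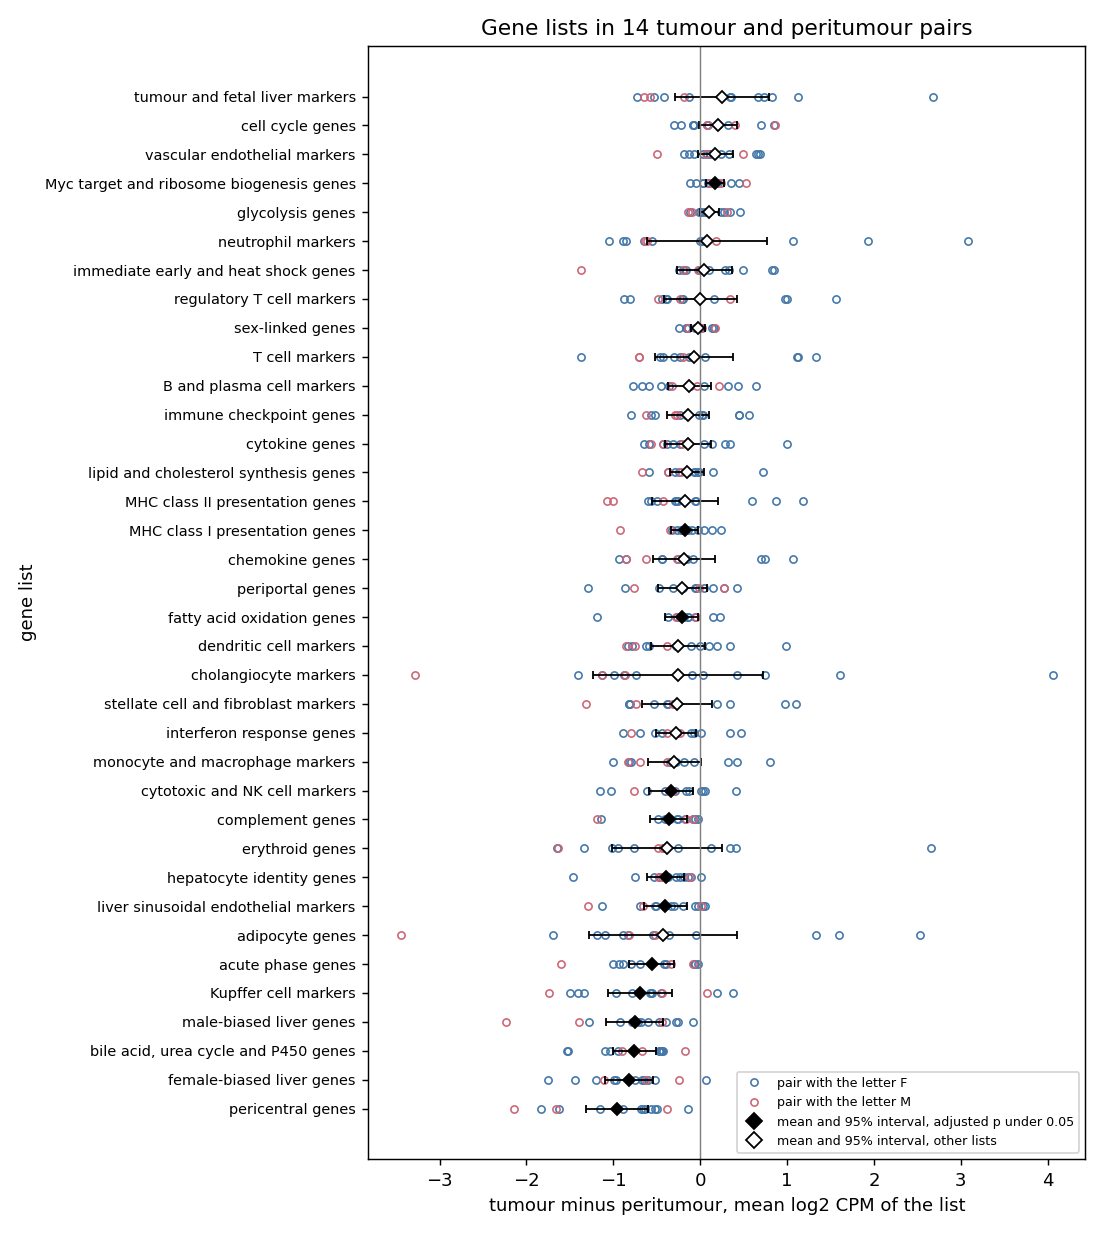
Difference between tumour and peritumour tissue in the mean log2 CPM of 36 gene lists. Open circles are the 14 animals (blue, letter F; red, letter M), diamonds the mean with its 95% interval, filled where the exact test passed an adjusted p of 0.05. The pericentral list lies lowest, with a mean of -0.956, and 12 of the 13 lists that passed are lower in tumour.

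Of the lists of immune cells and antigen presentation, Kupffer cell markers, cytotoxic and NK cell markers and MHC class I genes passed as lower in tumour. Kupffer cell markers fell by 0.693 (SD 0.647) in 11 of 14 pairs (exact adjusted p = 0.0083), and 5 of 8 members were lower, among them Vsig4, a complement receptor (-0.97 ± 0.18), and the lectin Clec4f (-0.93 ± 0.20). Without the block Clec4f did not pass (-0.77 ± 0.32, adjusted p = 0.184, edgeR). Cytotoxic and NK cell markers fell by 0.337 (SD 0.434) in 10 of 14 pairs (exact adjusted p = 0.0333), with Gzmb (-0.62 ± 0.15) and Xcl1 (-0.88 ± 0.27) the 2 members lower of 14. MHC class I presentation genes fell by 0.179 (SD 0.272) in 11 of 14 pairs (exact adjusted p = 0.0443), with 5 of 13 lower, among them B2m, the invariant light chain (-0.37 ± 0.09), and the transactivator Nlrc5 (-0.37 ± 0.09). The last 2 lists lie close to the threshold. The cytotoxic and NK list did not pass without F replicate 1, 6, 8, 9 or 11 or any M replicate (exact adjusted p from 0.0535 to 0.0667). The MHC class I list passed without F replicate 3, 4, 5 or 7 and not without any other pair (exact adjusted p from 0.0574 to 0.0835). In F pairs alone neither passed (exact adjusted p = 0.166 and 0.242). Sinusoidal endothelial markers, of the vessel cells that border hepatocytes, fell by 0.403 (SD 0.427) in 11 of 14 pairs (exact adjusted p = 0.0083), with Clec4g (-0.83 ± 0.17) and Dnase1l3 (-0.58 ± 0.14) lower of 7. Libraries with high counts of blood cell precursor genes were found in both tissues of F replicates 2, 5 and 6. The tumour of F replicate 4 was also high in them, but that pair was kept. Leaving out F pairs 2, 5 and 6, a choice made after their values were seen, gave a Kupffer mean of -0.60 and an MHC class I mean of -0.20. Then 22 of 36 lists passed in place of 13, of which 21 were lower in tumour in place of 12.

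**Figure D3:**
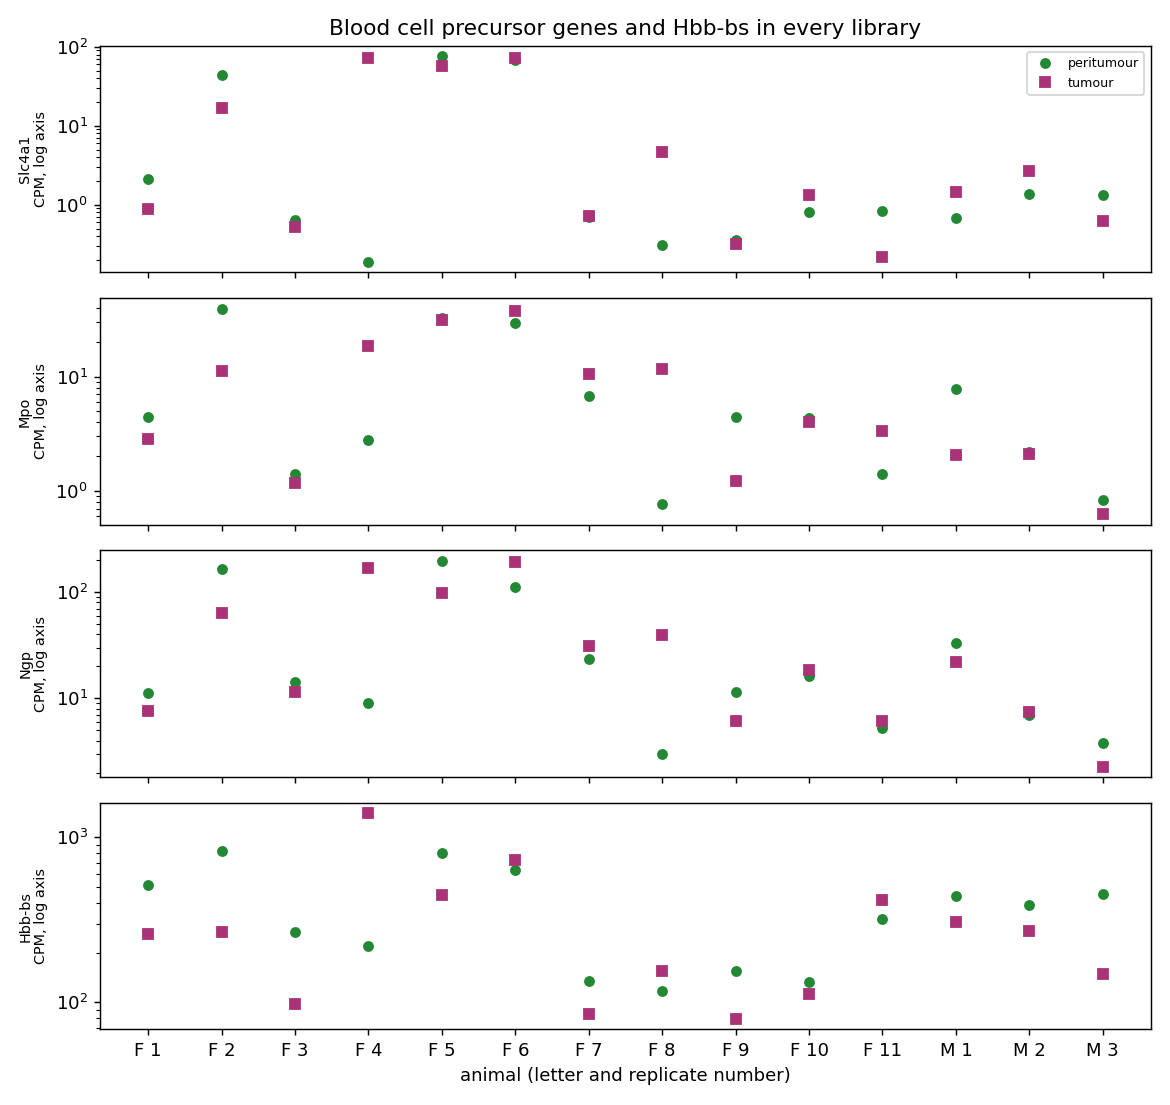
CPM of Slc4a1, Mpo, Ngp and Hbb-bs in both tissues of each animal, on a log axis. Slc4a1 reached 76.1 CPM in peritumour tissue against a median of 0.828 CPM, and Hbb-bs 820 CPM against a median of 356 CPM.

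The other immune lists did not pass as lists. Mean differences per pair were -0.07 for T cell markers (exact adjusted p = 0.795), 0.001 for regulatory T cell markers (0.998), -0.13 for B and plasma cell markers (0.372), -0.30 for monocyte and macrophage markers (0.132) and -0.26 for dendritic cell markers (0.19). They were 0.08 for neutrophil markers (exact adjusted p = 0.842), -0.17 for MHC class II genes (0.413), -0.14 for immune checkpoint genes (0.34), -0.19 for chemokines (0.372), -0.14 for cytokines (0.372) and -0.28 for interferon response genes (0.0606). Several of these means depend on F pairs 2, 5 and 6 as a set. The T cell difference was 1.33 in F replicate 2 and 1.12 in F replicate 5, though also 1.12 in F replicate 3, which is not among the 3 pairs. F replicate 6 added little, with 0.05 for T cell, -0.302 for monocyte and macrophage and 0.096 for dendritic cell markers. Without the 3 pairs the means were -0.32 for T cell markers, -0.25 for regulatory T cell markers, -0.45 for monocyte and macrophage markers, -0.46 for dendritic cell markers, -0.39 for MHC class II genes, -0.27 for immune checkpoint genes, -0.39 for chemokines and -0.31 for cytokines, and these lists other than T and regulatory T cell markers then passed as lower. Interferon response genes passed without F replicate 2 (exact adjusted p = 0.0184), F replicate 3 (0.0293) or the 3 pairs (0.0264), monocyte and macrophage markers without F replicate 2 (0.0331) and dendritic cell markers without F replicate 5 (0.0385). The neutrophil mean was -0.15 without F replicate 4. Single members that fell in the paired fit were the chemokines Cxcl9 (-0.68 ± 0.17) and Cxcl12 (-0.48 ± 0.09), 2 of 4 among 25, Ifih1 (-0.45 ± 0.13) of the interferon list, Il1a (-0.75 ± 0.18), the complement receptor Cr2 of B cells (-1.14 ± 0.36) and the dendritic cell receptor Clec9a (-0.60 ± 0.18). Cd274, which encodes PD-L1, had a paired log2 fold change of -0.34 ± 0.14 (adjusted p = 0.126, edgeR), Cd8a -0.03 ± 0.19 (0.927), Foxp3 0.21 ± 0.51 (0.821) and Ly6g 0.00 ± 0.44 (0.997). Foxp3 and Ly6g averaged under 1 CPM in both tissues, so changes in them were hardly detectable at this depth.

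Single stromal genes went both ways, and the lists of stromal and other cell types below did not pass over all pairs. Of 15 stellate cell and fibroblast markers (mean -0.27, SD 0.698; exact adjusted p = 0.278), Acta2, smooth muscle actin, rose (0.51 ± 0.16), and 4 fell, among them Lrat (-1.01 ± 0.16) and Reln (-0.65 ± 0.13). Vascular endothelial markers had a mean of 0.18 (SD 0.355; exact adjusted p = 0.174), with Apln the 1 of 9 that rose (1.54 ± 0.40). Cholangiocyte markers (-0.26, SD 1.69; exact adjusted p = 0.649), erythroid genes (-0.39, SD 1.1; 0.334) and immediate early and heat shock genes (0.05, SD 0.546; 0.809) did not pass. Without F pairs 2, 5 and 6 the mean was -0.55 for the stellate cell and fibroblast list (exact adjusted p = 0.0156) and -0.92 for the cholangiocyte list (0.0192). Erythroid genes passed without F replicate 4 (-0.62, exact adjusted p = 0.0242). Krt19, a bile duct keratin, had a paired log2 fold change of -0.38 ± 0.60 (adjusted p = 0.715, edgeR). Adipocyte genes, with 1 tested member, had a mean of -0.43 (SD 1.48; exact adjusted p = 0.389), and sex-linked genes -0.03 (SD 0.141; 0.55). None of the 7 pancreatic acinar genes passed the expression filter; their highest count in any library was 8.

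Set against all other genes by camera, 14 of 35 lists passed without pairing and 17 with the block at the preset correlation of 0.01. With an estimated correlation 0 lists passed in either fit; the smallest adjusted p was 0.158 without pairing and 0.057 with the block, for the P450, pericentral, male-biased and female-biased lists.

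Within the animals of letter F, tumour was compared with peritumour tissue in 11 pairs. Muc13 (4.00 ± 0.81), Anxa13 (2.32 ± 0.50), the adhesion protein Igsf9 (1.76 ± 0.33), Inava (1.42 ± 0.32) and Misp (1.36 ± 0.30) had the largest rises. Diaph2 (-0.71 ± 0.13), Mcts1 (-0.54 ± 0.12), the bicarbonate transporter Slc4a4 (-0.53 ± 0.12) and Vma21 (-0.43 ± 0.09) fell. In all, 37 genes were higher and 7 lower (edgeR, adjusted p from 0.0239 for Igsf9 and Diaph2), while with the animal as a block 650 were higher and 739 lower, without an excess of rises. A fit to the F libraries alone called 0 genes (edgeR), with 2105 at an unadjusted p under 0.05, and scaling by library size alone left 24 higher and 0 lower. Krt19 did not pass (1.13 ± 0.85, adjusted p = 0.493, edgeR).

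Within the 3 animals of letter M, no single gene passed in edgeR's test, with or without the block; 574 genes had an unadjusted p under 0.05, and DESeq2 called 3 genes. These were Styk1, higher in tumour (2.63 ± 0.52), Ifitm1, lower (-1.77 ± 0.37), and Dlk1, named here after their values were seen. Dlk1 had counts of 2, 0 and 1 in the Pe_M libraries and 0 in each Tu_M library, so it was hardly detected in M animals and no fold is given. The pericentral list averaged -1.40 (SD 0.909, n = 3) against -0.84 (SD 0.507, n = 11) in F animals, and Kupffer cell markers -0.70 (SD 0.934, n = 3) against -0.69 (SD 0.607, n = 11). The Kupffer cell values of M replicates 1, 2 and 3 were 0.076, -0.445 and -1.738, so that M mean rests largely on M replicate 3.

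Whether the tumour effect differed between M and F animals was tested as an interaction. No gene passed (edgeR), 423 had an unadjusted p under 0.05, and DESeq2 called 1 gene, Dlk1, which had at most 2 counts in any M library, so the call rests on a gene hardly detected there. Krt19 had a difference of -3.20 ± 1.76 on the log2 scale (adjusted p = 0.995, edgeR), and Myc 0.24 ± 0.43 (0.995). By exact permutation of the letters over animals, the smallest p for a list was 0.0275, for MHC class I presentation genes, whose tumour effect averaged -0.48 (SD 0.391) in M and -0.10 (SD 0.175) in F; adjusted over the lists this is 0.462.

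M and F animals were compared within each tissue. The 4 Y-linked genes were the ones that passed (edgeR) in both tissues. Ddx3y counts ran from 454 to 678 in Tu_M and from 340 to 783 in Pe_M, and were at most 1 in any F library. Kdm5d had 218 to 425 counts in Tu_M, 227 to 411 in Pe_M and 0 in every F library. Eif2s3y (424 to 616 and 415 to 692) and Uty (218 to 264 and 167 to 314) had at most 3 counts and 1 count in an F library. The unadjusted p was under 0.05 for 1389 genes in tumour and 215 in peritumour tissue. DESeq2 called 11 genes higher and 57 lower in tumour of M animals, and 4 higher and 2 lower in their peritumour tissue. These 4 were Ddx3y, Eif2s3y, Uty and Elovl3, without Kdm5d, and the 2 were Sult2a1 and Sult2a2. Elovl3, Sult2a1 and Sult2a2 are named here after their values were seen.

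Genes known to be higher in female than in male liver were lower in M in peritumour tissue. The female-biased list was lower by 1.47 on the log2 scale in M (mean 1.21, SD 0.571, n = 3) than in F (mean 2.68, SD 0.593, n = 11). The exact permutation p was 0.00275, the smallest the 364 splits can give, with adjusted p = 0.0495. That pass rests on a tie with the sex-linked list, made up of the 4 Y-linked genes, which had the same p in peritumour tissue. In tumour, where the sex-linked list alone had exact permutation p = 0.00275, its adjusted p was 0.0989. The male-biased list had a difference of 1.17 there and did not pass (exact permutation p = 0.0275, adjusted p = 0.33). In tumour the female-biased difference was -1.26 (exact permutation p = 0.00824, adjusted p = 0.148). Within the first code style, where 3 M and 3 F animals were compared, the peritumour difference of the female-biased list was -1.13 (exact permutation p = 0.1, the smallest possible). Against all other genes by camera with an estimated correlation, the female-biased list was lower in M in peritumour tissue (adjusted p = 0.0326) and the tumour and fetal liver markers were lower in M in tumour (mean -2.57, adjusted p = 0.0403). With that correlation the sex-linked list was higher in both tissues, and no other list passed camera. By exact permutation over animals the tumour and fetal liver markers did not pass (difference -1.39, p = 0.0577, adjusted p = 0.45). Afp was lower in M by point estimate in both tissues without passing (tumour -5.43 ± 2.58, adjusted p = 0.489; peritumour -4.64 ± 2.49, adjusted p = 1, edgeR).

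In the authors' deposited table, 11457 genes had a q-value under 0.05 for tumour against peritumour, 7531 higher and 3926 lower in tumour, and 1240 of the 11457 had a log2 fold change of at least 1 in size. All 1624 genes of the paired fit had a q-value under 0.05 and the same direction there. Both results come from the same libraries, and the 11457 are among 17346 genes with a q-value, so this overlap is not independent support. For M against F the authors' deposited table has 8519 such genes in peritumour tissue and 11940 in tumour, where edgeR called 4 in each. The authors' F means there leave out replicate 6, so their F groups may not be the 11 libraries used by edgeR. Their tumour and peritumour means take every library, yet that comparison too has many more genes (11457) than edgeR called. The cause of these gaps was not tested.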

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

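For the difference of the tumour effect between M and F animals, 11 gene lists passed camera at its preset correlation. With an estimated correlation 0 of these lists passed (smallest adjusted p = 0.631), and the exact test over animals gave an adjusted p of at least 0.462, so 3 M animals do not settle any of these differences. Mean differences of the log2 fold change, M minus F, were -2.48 for cholangiocyte markers, -1.26 for tumour and fetal liver markers, -0.86 for male-biased liver genes, -0.84 for immediate early and heat shock genes and -0.76 for MHC class II genes. They were -0.75 for stellate cell and fibroblast markers, -0.69 for T cell markers, -0.62 for chemokines, -0.55 for dendritic cell markers, -0.49 for monocyte and macrophage markers and 0.34 for cell cycle genes.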

How the results depend on the processing

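The tumour comparison without pairing (148 genes) moved to 64 with no filter, 622 in DESeq2, 62 with the fold change limit, 0 in either code style alone and 1624 with the replicate block; leaving out 1 pair gave 0 to 246, and leaving out F pairs 2, 5 and 6 gave 455, both chosen after the data were seen. RLE factors, library size alone and no covariates gave 147, 210 and 132. Tu_F against Pe_F (44) moved to 24 by library size alone, 10 with no filter, 9 with no code style term, 1389 (650 higher and 739 lower) with the replicate block, 0 in either style or in F libraries alone, 546 in DESeq2 and 15 with the fold change limit. The paired fit (1624) moved to 0 in the first style, 981 in the second and 212 with the fold change limit; without 1 pair it gave 899 (F replicate 8) to 1957 (F replicate 2), with 927 without F replicate 9 and 992 without F replicate 7. DESeq2 gave 3 for Tu_M against Pe_M, 1 for the interaction and 68 (11 higher and 57 lower) for Tu_M against Tu_F, which was 7 with no code style term. Leaving out M libraries in turn gave 0 for the first and second of these, 4 to 5 for the last and 4 for Pe_M against Pe_F. The count for Pe_M against Pe_F stayed within 4 to 6 over all settings. The genes did not all stay, as the 6 of DESeq2 held 3 of the 4 Y-linked genes. Scaling by library size alone shifted the median of all genes by -0.11 in Tu_M against Tu_F and in Pe_M against Pe_F, where the 4 Y-linked genes still passed. Lists past camera (14) went to 0 with an estimated correlation. Lists past the test per pair (13) went to 22 without F pairs 2, 5 and 6 and to 0 in either style alone, where 6 and 8 pairs are left; without 1 pair the count was 10 to 15. Myc ran from 0.28 to 0.43 and passed with the replicate block alone (0.34). For named genes 2216 of 2592 other values kept their direction and side of the threshold, 371 no longer passed, 5 newly passed and 0 reversed; for lists these were 53, 14, 3 and 0 of 70. Where it was run, the block changed no other count of genes, with 0 genes still passing in Tu_M against Pe_M and in the interaction; lists past camera were 17. Apart from the smaller samples of the single styles, the cause was not tested. Depth limits genes near 1 CPM, such as Foxp3.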

Other observations

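The pathway tests per pair and all tests below except the splits of samples were chosen only after the result was seen. Annotated pathways tested per pair gave 48 lower and 11 higher in tumour among 254. Against all other genes by camera in the paired fit, 55 passed at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.24). The largest falls were in retinol metabolism (-0.67, SD 0.378), linoleic acid metabolism (-0.66, SD 0.371) and steroid hormone biosynthesis (-0.64, SD 0.341), lower in 14, 13 and 14 of 14 pairs (exact adjusted p = 0.00345, 0.00413 and 0.00345). These pathways share many P450 genes. Peroxisome genes (-0.22, SD 0.211, 14 of 14 pairs), primary bile acid biosynthesis (-0.44, SD 0.4, 13 of 14) and fatty acid degradation (-0.32, SD 0.26, 13 of 14) were also lower (exact adjusted p = 0.00345, 0.00653 and 0.00705). Of the 11 higher in tumour, mannose type O-glycan biosynthesis had the smallest p (0.16, SD 0.115, 13 of 14, exact adjusted p = 0.00705). Streptomycin biosynthesis (0.199) and other types of O-glycan biosynthesis (0.194) had the largest means (exact adjusted p = 0.0111 and 0.014). Also higher were the ribosome (0.13, SD 0.134, 11 of 14), spliceosome (0.11, SD 0.107, 11 of 14), RNA polymerase (0.14, SD 0.132, 12 of 14) and base excision repair (0.16, SD 0.165, 11 of 14), with exact adjusted p = 0.0304, 0.0238, 0.0139 and 0.0219. DNA replication (0.18, SD 0.219, 11 of 14) and cell cycle (0.11, SD 0.14, 10 of 14) passed narrowly, each with exact adjusted p = 0.0499. Ribosome biogenesis in eukaryotes did not pass (0.07, SD 0.161, 9 of 14, exact adjusted p = 0.286).

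Other splits of the samples were tried. Tumour and peritumour labels were swapped within animals. Only the real split, 1 of 100, gave as many genes as the 148 without pairing (highest other 0). The same held for the 1624 of the paired fit (highest other 21) and the 44 of Tu_F against Pe_F (highest other 0). Random swaps thus seldom gave such counts, though 100 splits cannot show a share below 1 of 100. The 148 still fell to 0 without some single pairs, and the 44 fell to 0 in F libraries alone. For Tu_M against Pe_M only 4 splits exist, too few for a share under 0.05; the real count was 0 and the highest other 0. The letter M was also given to 3 other animals. The interaction has a real count of 0, which all 100 of 100 splits must reach (highest other 381), so these splits decide nothing about it. For Tu_M against Tu_F, 39 of 100 splits gave at least 4 genes (highest other 2571), so a count of 4 by itself does not exclude chance. The 4 genes themselves are Y-linked, with at least 218 counts in every Tu_M library and at most 3 in any Tu_F library. The exact permutation p of their list is 0.00275, the smallest of 364 splits, and 0.0989 adjusted over the lists. Both highest values came from F replicates 2, 3 and 5 as a set, which points to a structure of the samples. For Pe_M against Pe_F, 3 of 100 splits, the real one among them, gave at least 4 genes (highest other 39). That share is under 0.05, but other splits reached the count too, so it does not by itself exclude chance. The 4 genes there are the same Y-linked ones.

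The lower pericentral, P450 and Kupffer cell genes in tumour may reflect a smaller share of hepatocytes in the tumour pieces, scaling or shared reads. A smaller share of hepatocytes would lower pericentral and periportal genes alike. Yet the pericentral list differed from the periportal list by -0.752 (SD 0.782, 95% interval -1.2 to -0.301, below 0 in 12 of 14 pairs). Both list means had been seen before this comparison was chosen, so it is not an independent test. The gap argues against a smaller share of hepatocytes as the whole cause of the pericentral fall, if both lists are equally specific to hepatocytes. A smaller share may still be a part of it, as hepatocyte identity genes fell by 0.397 in 13 of 14 pairs. Scaling by library size alone left the pericentral mean at -0.925 and the Kupffer cell mean at -0.661, which argues against scaling for these lists. In the paired fit with TMM factors 7 of the 8 pericentral members outside the P450 family passed as lower. That count follows from the members already given as lower in the results, so it is not a further test. Reads shared between P450 paralogs cannot account for those members, but stay open for the P450 genes themselves. For the Kupffer cell list only the choice of scaling was tested. A difference between tumour and peritumour tissue in hepatocyte zonation remains a hypothesis, found and tested on the same data, as does the position of the sampled pieces, which the labels do not give.

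Code style might mark a batch. Among Pe_F libraries, 3 of the first style against 8 of the second, edgeR called 0 genes, with 1589 at an unadjusted p under 0.05. Over 13389 genes, which are not independent replicates, transcript length accounted for 1.03% of the variance of the log2 fold changes. GC content accounted for 14.6% (Spearman rho 0.32 over genes). That variance also holds differences between animals and sampling noise, so these shares cannot bound a bias between the styles. A length bias and a GC bias both stay open. Animals of the styles are different animals, and no biological explanation was tested.

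Blood cell precursor genes were high in a few animals, and residual blood is a candidate explanation. Slc4a1, the red cell anion exchanger, reached 76.1 CPM in peritumour tissue against a median of 0.828 CPM, and Mpo and Ngp, of granulocyte precursors, 39.5 and 197 CPM against medians of 4.34 and 12.9 CPM. For Slc4a1 the animals are F replicates 2, 5 and 6 in both tissues and F replicate 4 in tumour, while Mpo was less distinct in the tumour of F replicate 2 (11.3 CPM, against 11.7 CPM in the tumour of F replicate 8). Hbb-bs, a main red cell transcript, spanned a ratio of 7.03 from the lowest to the highest peritumour library and reached 2.3 times its median. Slc4a1 reached 91.9 times its median, which argues against residual blood of constant makeup. In peritumour tissue Hbb-bs was nevertheless highest in the same animals, at 820, 804 and 634 CPM in F replicates 2, 5 and 6. In tumour it was highest in F replicate 4 (1400 CPM). It was 732, 444 and 266 CPM in the tumours of F replicates 6, 5 and 2, against a median of 262 CPM. Residual blood of another makeup stays open. The libraries form separate clusters, so no correlation is given, and no biological explanation was tested.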
